A study of Mus musculus with 78 samples.

How the data were processed

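Gene expression was measured in olfactory bulb and forebrain of genetically engineered mice on 2-colour Agilent arrays. Per the labels, RNA of each sample carried the dye Cy5 and a commercial pool of mouse RNA carried Cy3 on the same array, with 1 dye orientation throughout. The deposited table held 33554 probes and 78 arrays with 0 missing values. Per the submitters' processing notes, Agilent Feature Extraction was used; its version, the background correction and the normalization are not given in the sources used here.

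The deposited values were log ratios, read as log2 ratios of sample over reference. The base was not stated. The values ran from -8.49 to 9.28, a range that base 10 would make implausibly wide. The direction is likely sample over reference, from the dyes in the labels; the table itself did not state it. The lowest correlation between any pair of arrays was 0.763, so no array ran against the others, and the opposite convention would turn every higher into lower and leave counts and sizes as they are. Array medians lay between 0.006 and 0.078, so the arrays had been centred close to 0 by a step that was not stated. Intensities and backgrounds were not used here, so dim probes could not be removed and the signal behind a probe is unknown; the number of arrays limits the precision.

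Samples were grouped by the genotype and tissue in the labels, which also gave an animal number and 1 of 8 batches per array. Titles of the control arrays called the 4 bulbs Oil and the 3 forebrains Normal, also where 1 animal gave both tissues. Titles of the other genotypes named no treatment, so an oil treatment of the controls alone could not be told apart from genotype in comparisons with control. The interaction of T and R and the bulb effects of each with and without the other, described below, set no control arrays against other genotypes. The 78 arrays came from 56 animals, so arrays within a tissue were separate animals. In all, 21 animals had a grouped array of each tissue. For 1 forebrain array the title and the genotype field disagreed, and it entered no group. No table pairing these probes with genes was used here, so results are given per probe, probes are named by their identifiers, and gene lists fixed in advance, an average over the probes of a gene and a check of the targeted genes were not run. The planned tests assumed values averaged per gene.

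Each comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the values as deposited, with Benjamini-Hochberg adjustment over all 33554 probes and a threshold of 0.05, two-sided. Errors given with log2 differences are standard errors of the fit unless called SD. All grouped arrays of a tissue entered 1 fit with genotype and batch as fixed terms. The effects of T, R and each form of P came from a fit with additive terms for them and for batch. The interaction of T and R was (TRP - RP) - (TP - P), averaged over the het and null forms of P. The difference between tissues was fitted on the 21 animals with both, with the animal as a fixed block, because the labels tie the arrays of an animal by its number. The difference between the tissue effects used all 77 grouped arrays with the animal as a random block, whose estimated correlation was 0.14, computed on every 5th probe. A noise-corrected size of change is the root mean square log2 difference over all probes after the mean squared standard error was subtracted. The probes named are the 2 with the largest rise and the 2 with the largest fall among those past the threshold; for comparisons of 2 genotypes every array of the first also had to lie on that side of the mean of the second. These choices were made before the data were examined, except that the number of names was lowered to 2 for want of gene names.

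Additive effects in the forebrain, the effects of T and of R with and without the other, and a T score were added after the data were seen. The T score of an array was the mean log2 ratio of the probes that rose with T minus that of the probes that fell, with the probes taken from the fit of the other tissue. Its groups were compared by two-sided exact permutation tests, and its interaction by a permutation test with 100000 resamples. The spread of an array was its root mean square log2 deviation from the mean of the other arrays of its genotype and tissue.

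The fits were tested on simulated data with known changes, made of independent normal noise per probe with 66 or 67 probes changed at each size. Real probes are not independent, so the shares recovered are only a guide to what the fits could find in the data. A log2 change of 1 was recovered at 73.1% of the changed probes for TRPnull against control in the bulb, at 100% for the additive effects of T and of R there, at 95.5% for those of Phet and Pnull, and at 11.9% for TRPnull against control in the forebrain. Alternatives were batch left out, batch as a random block, quantile normalization, median centring, the more variable part of the probes, array weights (whose estimation stopped short of its tolerance in some fits), the compared groups alone, single batches, and each array of small groups left out in turn. Other splits of the same arrays were refitted, at most 100 per comparison. Figures were drawn with matplotlib 3.10.9.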

Results

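Expression was compared in 2 brain regions, the olfactory bulb and the forebrain, of mice carrying combinations of engineered drivers named T, R and P in the labels. The labels do not spell these letters out. P came in a het and a null form. The series set out to compare transcriptomes across drivers and locations. The bulb gave 52 arrays of 12 genotypes: control 4, T 4, R 2, TR 1, Phet 4, Pnull 5, TPhet 5, TPnull 5, RPhet 4, RPnull 5, TRPhet 8 and TRPnull 5. The forebrain gave 25 grouped arrays of 8 genotypes: control 3, T 4, TR 2, TPhet 3, RPhet 1, RPnull 1, TRPhet 6 and TRPnull 5. Each value was the log2 ratio of a sample to a common reference RNA, so levels compare between arrays but not between probes.

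The main divisions among the arrays were T and tissue. The first principal component, with 37.1% of the variance, ran from bulbs without T to arrays with T and R. On the second, with 13.9%, forebrain arrays lay mostly above bulbs, and the tissues parted on both components together. Bulbs with P, R or RP lay beside the control bulbs. Within the bulb, presence of T accounted for 32.4% of the variance, the full genotype for 52.2% and batch for 4.2%. The third component, with 10.6%, was led by 3 arrays: forebrain control replicate 3, bulb T replicate 3 and bulb RPnull replicate 1.

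**Figure D1:**
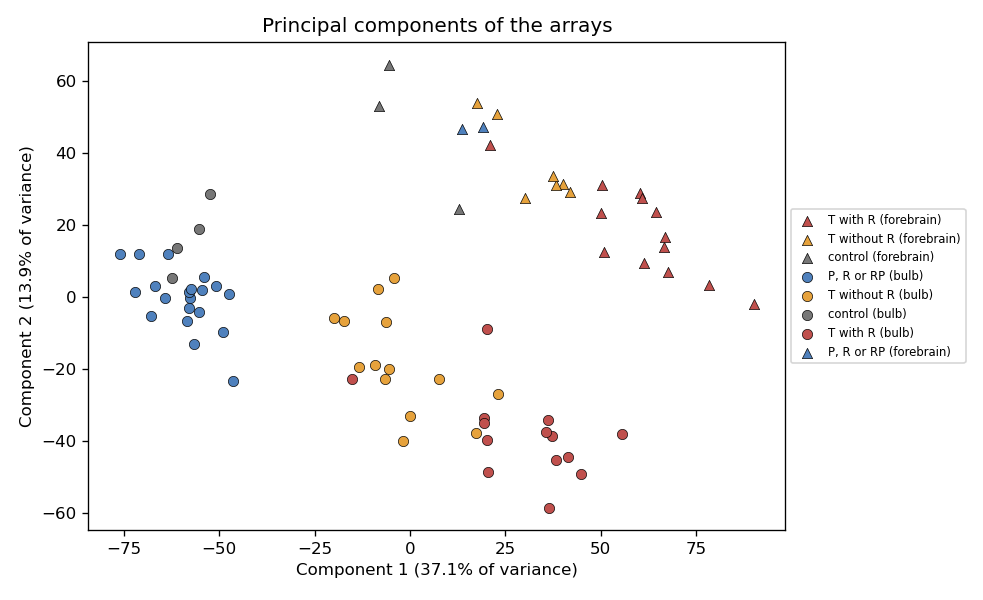
Scores of the 77 grouped arrays on components 1 (37.1% of the variance) and 2 (13.9%), circles for olfactory bulb and triangles for forebrain, coloured by driver class. Bulbs without T lie at the left, bulbs with T and R at the right, and the red circle among the T bulbs without R is TRPnull replicate 5.

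T changed the olfactory bulb more than any other driver tested there. Across 28 bulbs with T and 24 without, 16854 probes passed the threshold, 7238 higher and 9616 lower, or 50.2% of all probes. The rises were the larger changes: 1055 probes rose and 35 fell by at least 1 on the log2 scale. Probe A_51_P230098 was 25-fold higher (log2 difference 4.64 ± 0.18; limma adjusted p = 5.1e-25), with ratios of -0.28 ± 0.81 (SD, n = 28) with T and -4.83 ± 0.39 (SD, n = 24) without. A_51_P195034 rose by 4.56 ± 0.20. The largest falls were smaller, -1.32 ± 0.12 for A_51_P205215 and -1.30 ± 0.22 for A_52_P669035.

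T alone, against control bulbs, changed 5013 probes, 2491 higher and 2522 lower (4 arrays each). A_51_P130015 was 12.6-fold higher (3.66 ± 0.43) and A_51_P195034 12.2-fold higher (3.61 ± 0.46). A_52_P344949 was lower by -2.07 ± 0.61 and A_51_P149579 by -2.02 ± 0.54. A_52_P344949 was not called without T replicate 2 (-1.93), T replicate 3 (-1.54) or control replicate 4 (-1.92). The count rested on single arrays: it was 2464 without T replicate 3, 2412 without control replicate 4 and 3279 without control replicate 3. Within batch 3 the difference kept the sign of 70.7% of the probes called in the other batches, and within batch 5 of 97.4%, with 1 control array in each.

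T together with P also changed the bulb. TPhet changed 2884 probes, 2000 higher and 884 lower, and TPnull 2491, 1665 higher and 826 lower (5 arrays each against 4 controls). A_51_P195034 rose in both, by 4.06 ± 0.43 in TPhet and 3.45 ± 0.43 in TPnull, A_51_P130015 by 4.15 ± 0.41 in TPhet and A_52_P251366 by 3.43 ± 0.41 in TPnull. A_51_P178692 had the largest fall in both, -1.81 ± 0.52 in TPhet and 4.01-fold in TPnull. It was not called in TPhet without replicate 1 (-1.63) or 3 (-1.64) or control replicate 1 (-1.61) or 4 (-1.70), nor in TPnull without replicate 3 (-1.68) or control replicate 1 (-1.80) or 4 (-1.90). The difference between these genotypes and T was not tested, and the order of their counts depended on the fit, with 2967 for TPhet, 1302 for TPnull and 1175 for T when the compared groups were fitted alone. The TPhet count was 1606 without control replicate 1, 1794 without control replicate 4 and 1804 without TPhet replicate 5, and the TPnull count was 1374 without control replicate 4 and 1652 without TPnull replicate 3. Within the batches that held both groups, 3, 4 and 5, with 1 array of the genotype and 1 or 2 controls, the differences kept the sign of at least 98% of the probes called in the other batches for TPhet and of 90.6%, 86.4% and 99.6% for TPnull.

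The triple genotypes had the most changed probes of any genotype compared with control bulbs. TRPhet changed 10431 probes, 4798 higher and 5633 lower (8 arrays against 4), and TRPnull 11285, 5231 higher and 6054 lower (5 against 4). In TRPnull 1759 probes rose and 1325 fell by at least 1 on the log2 scale. A_51_P246653 was 37.8-fold higher in TRPnull (5.24 ± 0.60; limma adjusted p = 1.3e-08), at 0.55 ± 1.3 (SD, n = 5) against -4.59 ± 0.36 (SD, n = 4), and 36.2-fold higher in TRPhet. A_51_P137419 was 24.6-fold higher in TRPnull (4.62 ± 0.44) and A_51_P432641 29.4-fold higher in TRPhet (4.88 ± 0.64). A_52_P37991 was lower in both, by -2.96 ± 0.40 in TRPnull and -1.91 ± 0.37 in TRPhet, and A_51_P181354 by -2.39 ± 0.64 in TRPnull. Within batches 3, 4 and 5, with 1 array a side in 3 and 5 and 2 in 4, the TRPnull differences kept the sign of 96.1%, 99.6% and 97.5% of the probes called in the other batches, and the TRPhet differences of 92.3%, 99.3% and 93.1%.

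**Figure D2:**
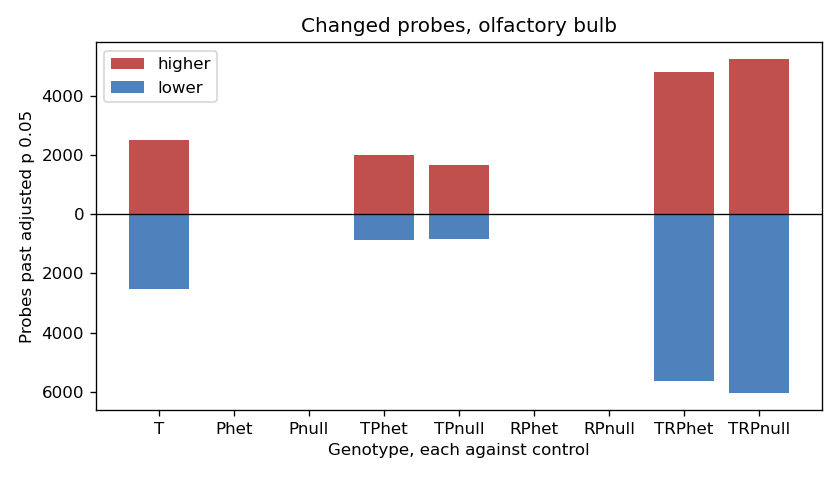
Number of probes past an adjusted p of 0.05 in each genotype against control, olfactory bulb, higher in red above 0 and lower in blue below 0. Phet, Pnull, RPhet and RPnull have 0, and TRPnull has 11285.

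P, alone or with R, left no probe past the threshold in bulbs without T. R alone (2 arrays) was not compared with control. Phet and control bulbs shared no batch, so their comparison rests on batch terms estimated through other genotypes. RPhet and RPnull each shared only batch 5 with the controls, with 1 array a side. Against control, limma called 0 probes in Phet (1705 at an unadjusted p under 0.05, or 5.08%), 0 in Pnull (1830, 5.45%), 0 in RPhet (935, 2.79%) and 0 in RPnull (2586, 7.71%). Averaged over the other drivers, Phet changed 0 probes (3213 unadjusted) and Pnull 0 (3206 unadjusted; lowest adjusted p = 0.062), and Pnull did not differ from Phet (0 called, 879 unadjusted). On simulated data, a log2 change of 1 was recovered at 71.6% of changed probes for Phet and 65.7% for RPhet, and a change of 0.5 at 10.4% and 11.9%. For the averaged effects of Phet and Pnull a change of 0.5 was recovered at 56.7% and 71.6%, and for Pnull against Phet at 91%. The P effects passed the threshold under other treatments of batch, with 1418 probes for Phet and 381 for Pnull when batch was a random block, and Pnull against control reached 972 probes with array weights.

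R changed the bulb only in the presence of T in these comparisons. Averaged over the other drivers, R changed 3035 probes, 1782 higher and 1253 lower (25 arrays with R, 27 without). Among arrays with T and P it changed 8092, 3944 higher and 4148 lower, and among arrays with P and no T it changed 0 by limma (515 at an unadjusted p under 0.05). The interaction of T and R, which tests that difference, passed the threshold at 1719 probes, 1116 positive and 603 negative. A_51_P351975 stood at -3.94 ± 0.47 (SD, n = 9) in P, -3.89 ± 0.48 (SD, n = 9) in RP, -3.69 ± 0.56 (SD, n = 10) in TP and -0.61 ± 0.52 (SD, n = 13) in TRP bulbs, an interaction of 2.99 ± 0.39 (limma adjusted p = 1.3e-05). Bulb T replicate 1, labelled without R and outside this contrast, stood at -1.33 at A_51_P351975. The other T bulbs stood at -3.56, -3.94 and -4.28, and the label of replicate 1 was not tested. A_51_P431329 had an interaction of 2.83 ± 0.40.

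At A_52_P707503 the drivers acted in opposite directions. Its ratio was -0.91 ± 0.65 (SD, n = 9) in P and -0.98 ± 0.65 (SD, n = 9) in RP bulbs, 3.44 ± 0.38 (SD, n = 10) in TP and 1.69 ± 0.96 (SD, n = 13) in TRP. T raised it by 4.64 ± 0.30 without R, and R lowered it by -1.87 ± 0.25 with T, an interaction of -1.79 ± 0.37 (limma adjusted p = 0.0035). At A_52_P707503 bulb T replicate 1 stood at 1.29 and the other T bulbs at 2.7, 3.22 and 2.63. A_52_P876147 had an interaction of -1.99 ± 0.35. T itself changed 13368 probes in the presence of R and 5107 in its absence. The interaction count rose to 2827 with batch left out and to 4490 with array weights.

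**Figure D3:**
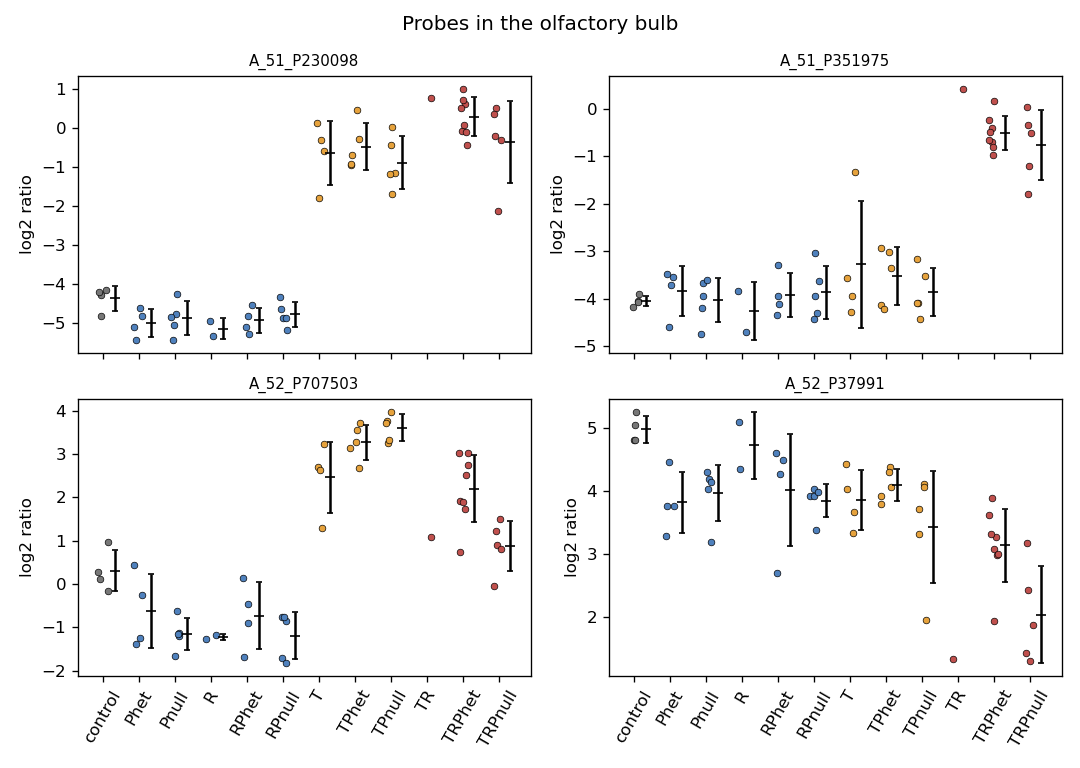
Log2 ratios of 4 probes in each olfactory bulb array by genotype, with mean and SD beside the points of genotypes with more than 1 array (grey control, blue P, R or RP, orange T without R, red T with R). A_51_P230098 is high wherever T is present, A_51_P351975 averages -0.61 in TRP and -3.94, -3.89 and -3.69 in P, RP and TP, and A_52_P707503 is higher in TP than in TRP. Bulb T replicate 1, labelled without R, stands at -1.33 at A_51_P351975.

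The null and het forms of P differed at 1 probe in the triple genotype of the bulb. A_51_P460332 was 2.05-fold higher in TRPnull than in TRPhet bulbs (1.03 ± 0.17; limma adjusted p = 0.012), at 1.24 ± 0.42 (SD, n = 5) against 0.28 ± 0.32 (SD, n = 8). It was no longer called without TRPnull replicate 3 (0.85), without replicate 4 (1.04) or when these genotypes were fitted alone (1.25), with 0 probes each, and the count was 20 with batch left out. In the forebrain the same comparison called 0 probes (1265 unadjusted, limma), and its differences in batch 1 (4 arrays a side) and batch 8 (1 TRPnull array, 2 TRPhet) correlated at -0.26 across probes.

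T also changed the forebrain, mostly upward in the additive fit of all arrays. Across 20 arrays with T and 5 without, 2107 probes passed the threshold, 1658 higher and 449 lower. The additive fit was not repeated without control replicate 2, on which the direction rested in single genotypes (below). The leading probes were the ones that led in the bulb: A_51_P230098 rose by 3.42 ± 0.34 and A_51_P195034 by 3.40 ± 0.40. A_52_P560113 fell by -1.52 ± 0.44 and A_52_P213916 by -1.11 ± 0.30, and neither was called without control replicate 3 (-1.27 and -0.96). Of the probes called in both tissues, 1523 rose in both, against 357.7 for independent lists, 291 fell in both, against 128.7, and 25 went opposite ways. The effects correlated at 0.67 across probes, which are not independent, and 21 animals gave arrays to both sides. The forebrain effect of R passed the threshold at 0 probes (3670 unadjusted, limma), but at 2162 when batch was a random block, 885 with batch left out and 1279 with array weights. All arrays of batch 1 carried R and no grouped array of batch 2 did. The counts with batch random or left out therefore cannot separate R from batch. On simulated data its fit recovered a log2 change of 0.5 at 9% of changed probes and of 1 at 64.2%.

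**Figure D4:**
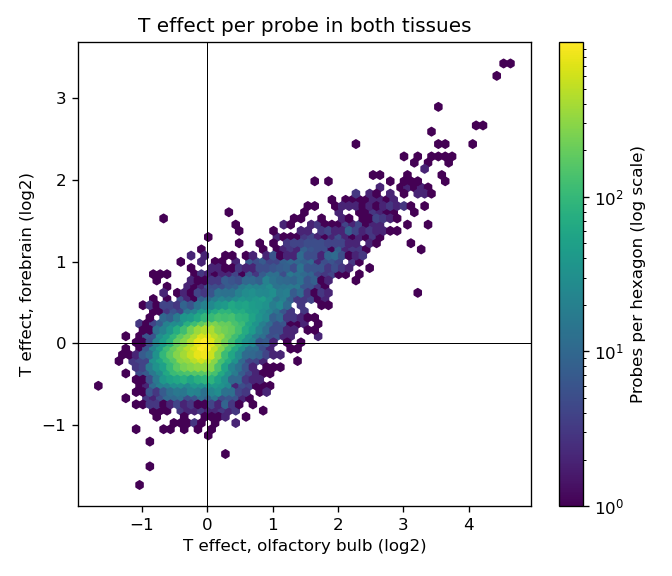
Effect of T on each of the 33554 probes in olfactory bulb (horizontal) and forebrain (vertical), log2, with the number of probes per hexagon on a log colour scale. Most large rises lie at the upper right, and the correlation across probes is 0.67.

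Single genotypes in the forebrain were compared with 3 controls, all in batch 2. T changed 541 probes, 487 higher and 54 lower (4 arrays), led by A_51_P195034 at 3.45 ± 0.63 and A_51_P217498 at 3.37 ± 0.38, with A_52_P545914 at -1.80 ± 0.44 and A_52_P67212 at -1.50 ± 0.29. TPhet changed 147, 124 higher and 23 lower (3 arrays), led by A_51_P217498 at 3.05 ± 0.38 and A_51_P230098 at 2.98 ± 0.55, with A_52_P216672 at -1.65 ± 0.36 and A_51_P368894 at -1.47 ± 0.32. With single arrays left out, A_51_P217498 was called throughout in both, and each of the other probes named lost its call at least once. A_52_P545914 was also not called in T without T replicate 3 (-1.77) or 4 (-1.81). Both counts rested on single arrays. Without control replicate 2 they were 3018 and 4373, and without control replicate 3 they were 227 and 1. The direction also rested on control replicate 2. Without it, 41% of the T calls and 35.1% of the TPhet calls were higher, against 90% and 84.4% with all arrays. Without control replicate 1 they were 7 and 1, without T replicate 1 or 2 the T count was 2 or 1, and without TPhet replicate 1, 2 or 3 the TPhet count was 2, 1 or 1.

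For the triple genotypes of the forebrain, the count depended on the batch term. With it, TRPhet changed 0 probes (6433 unadjusted; lowest adjusted p = 0.0525, limma) and TRPnull changed 5, 2 higher and 3 lower (6123 unadjusted). The 5 included A_52_P446171 at 1.78 ± 0.29, A_52_P368008 at 1.42 ± 0.22, A_52_P653678 at -2.10 ± 0.35 and A_52_P376214 at -1.66 ± 0.26. Without the batch term the counts were 6959 and 7277. No batch held both these genotypes and the controls, so a value within a batch could not be had. The TRPnull count was 2363 without replicate 5, 2237 without control replicate 2, 1 without replicate 2 and 0 without replicate 1, 3 or 4 or without control replicate 1 or 3; the TRPhet count was 2339 without control replicate 2.

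Bulb and forebrain of the same animal differed at 16804 probes, 6913 higher in the bulb and 9891 higher in the forebrain (21 animals). Only 2 controls, 1 RPhet and 1 RPnull animal lacked T. The noise-corrected size of the additive T effect was 0.431 in the bulb and 0.252 in the forebrain. The list can therefore hold effects of T that differ between tissues, beside the difference between tissues itself. A_51_P390038 was 21-fold higher in the bulb (4.39 ± 0.18; limma adjusted p = 1.4e-15) and A_52_P669035 17.8-fold higher (4.15 ± 0.19). A_51_P494293 was higher in the forebrain (-4.05 ± 0.28), as was A_52_P536927 (-3.86 ± 0.18). A_52_P669035 was also among the 2 probes that T lowered most in the bulb. Tissue and batch coincided in all but the 2 animals of batch 8 whose tissues shared it. In those 2, the differences kept the sign of 91.6% of the probes called in the other animals, with a correlation of 0.82 across probes.

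The change from control to TRPnull differed between the tissues at 3 probes. The difference, bulb minus forebrain, was 3.14 ± 0.61 at A_52_P337126, 1.5 ± 0.29 at A_52_P78770 and -1.21 ± 0.23 at A_52_P665520 (limma adjusted p = 0.042 for each). For TRPhet 0 probes passed (5488 unadjusted, limma). None of the 3 was called under quantile normalization (3.03, 1.63 and -1.17) or median centring (3.10, 1.46 and -1.25), though the differences hardly moved, nor with batch left out (1.60, 0.92 and -0.64), where they shrank. The calls were also lost with array weights (2.89 and 1.40 at the 2 with positive differences) and without the 3 arrays far out on the third component (2.94, 1.40 and -1.12).

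A T score summarised these changes per array, as the mean log2 ratio of the probes that rose with T minus that of the probes that fell, with the probes taken from the other tissue. Because 21 animals gave arrays to both tissues, the choice of probes was not independent of the animals scored. In the bulb it was higher than in control by 1.03 in T, 1.33 in TPhet, 1.14 in TPnull, 1.71 in TRPhet and 1.60 in TRPnull (two-sided exact permutation p = 0.0286, 0.00794, 0.0159, 0.00202 and 0.00794). In Phet, Pnull, RPhet and RPnull it differed from control by 0.0266, 0.0775, 0.0148 and 0.0186 (exact p = 0.943, 0.508, 0.886 and 0.889). The lowest of the 28 bulbs with T stood at -1.51 and the highest of the 24 without at -1.67. Within batches 3 to 7 the mean difference between bulbs with and without T was 1.67, 1.31, 1.27, 1.14 and 1.65. R raised the score by 0.431 with T and changed it by -0.038 without, an interaction of 0.469 (permutation p = 0.005). Without control replicate 1, 2, 3 or 4 the difference for T was 0.937, 1.01, 1.09 or 1.06, each with an exact p of 0.0571.

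In the forebrain the T score rose by 0.480 in T (two-sided exact p = 0.0286) and 0.817 in TRPhet (exact p = 0.0119). All animals of the forebrain T group, and those of control replicates 2 and 3, also gave bulbs to the fit that chose the probes. TRPnull differed from control by 0.821 (exact p = 0.0536) and TPhet by 0.306 (exact p = 0.3, where 3 arrays against 3 cannot go below 0.1). All controls were in batch 2 and TRPhet and TRPnull in batches 1 and 8, so those p values cannot separate genotype from batch, and arrays without T in batch 8 averaged -1.29, against -1.52 in the controls. Arrays with and without T overlapped, and the mean difference between them was 0.336 within batch 2 and 0.408 within batch 8. For T, the exact p was 0.0667 without control replicate 1, 2 or 3 (differences 0.419, 0.412 and 0.609) and 0.1 without T replicate 1, 2, 3 or 4 (0.505, 0.468, 0.466 and 0.481), the smallest such numbers allowed. For TRPnull it was 0.0476 without control replicate 3 (0.950) and 0.0286 without TRPnull replicate 5 (0.968), and with quantile normalization it was 0.0357 (0.881).

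**Figure D5:**
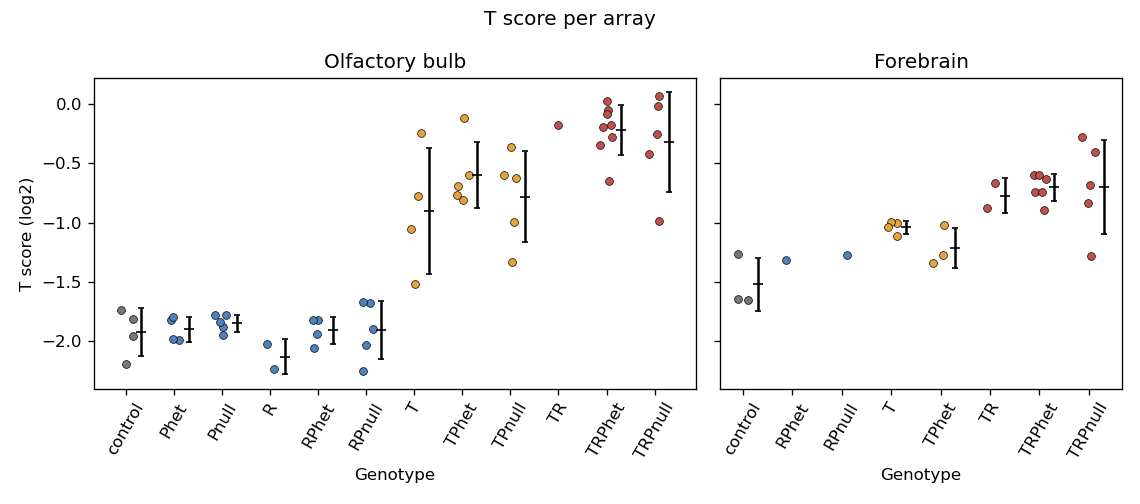
T score of each array in log2 by genotype and tissue, with mean and SD for genotypes with more than 1 array (grey control, blue P, R or RP, orange T without R, red T with R). Bulbs with T lie at or above -1.51 and bulbs without T at or below -1.67, while forebrain arrays with and without T overlap.

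The spread among arrays of a genotype gave no firm difference between TRP and control. In the bulb the root mean square deviation of an array from the others of its genotype was 0.336 ± 0.0647 (SD, n = 13) in TRP and 0.263 ± 0.0467 (SD, n = 4) in control (two-sided exact permutation p = 0.0542). In the forebrain it was 0.326 ± 0.0592 (SD, n = 11) against 0.441 ± 0.143 (SD, n = 3; two-sided exact permutation p = 0.044). A deviation from the mean of few arrays is larger by construction, and scaling for the number of arrays turned both calls, with a difference of 0.0807 in the bulb (exact p = 0.0239) and -0.0654 in the forebrain (exact p = 0.165). With quantile normalization the exact p was 0.00546 in the bulb and 0.275 in the forebrain. Single arrays decided both calls: in the bulb the exact p was 0.0357 without control replicate 1 and 0.0484 without TRPnull replicate 4, and in the forebrain it was 0.231 without control replicate 3, 0.0594 without TRPnull replicate 1 or 2 and 0.0804 without TRPnull replicate 3.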

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

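The T score, the effects of R with and without T, the counts over other splits of the arrays, the precision test of the forebrain fits, and the tests of TRPnull replicate 5 on batch 8, on T, on separating probes and on an exchange of labels were chosen after the result was seen, and the rules of those on T and on the exchange were revised after their values were seen, which turned the former from open to excluded and the latter from excluded to open; the others were set beforehand.

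Of 76 groups of 4 to 10 arrays searched for a value far from the rest, 3 held one, and chance marks about 1 in 20 groups, so these 3 are no more than chance alone would give. Forebrain TRPhet replicate 5 had a spread of 0.4, against 0.261 to 0.294 in the other arrays of its group. Bulb Phet replicate 3 had a spread of 0.318, against 0.28 to 0.285. The log2 ratio of A_52_P37991 in bulb TRPhet replicate 8 was 1.94, against 2.99 to 3.90 in the others.

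A difference between groups in the effect of 1 driver or genotype was found by test in 2 places. The effect of R in the bulb differed with T at 1719 probes, a count that 2 of 100 splits reached, the real one included. These splits exchanged arrays among all genotypes of the contrast and so broke up the effect of T as well. They cannot exclude chance for the interaction itself. The highest other split gave 4164 probes, and its contrast put a net weight of 0.74 on arrays with T, against 0 in the real one and a median of 0.25, so its count can hold the effect of T itself. The change from control to TRPnull differed between tissues at 3 probes, a count reached by 8 of 100 splits, with 8593 the highest other, so chance was not excluded. That split put a net weight of 1.6 on arrays with T, against 0 in the real contrast and a median of 0.28.

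R changed 8092 probes with T and 0 without it in the bulb (515 at an unadjusted p under 0.05, limma). Fewer arrays without T was argued against, since draws of 9 arrays a side among T arrays called at least 3995 probes (median 6017). Batch differences were argued against by a median of 95.2% of calls from the other batches that held their sign within a batch, with 78.9% in batch 5 and 36% in batch 8. Batch 8 ran against the others. It had 1 array a side, TRPnull replicate 5 and TPhet replicate 5, whose labels are weighed below. A dependence of R on T may therefore be biological, as a hypothesis found and tested on the same arrays.

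In the forebrain, TRPhet and TRPnull differed from controls at 6959 and 7277 probes without a batch term and at 0 and 5 with it (6433 and 6123 unadjusted, limma). Batch alone was argued against: of 6546 probes called between TRP arrays of batch 1 and controls of batch 2, 84.2% held their sign between TRP and RP arrays within batch 8 (56.1% to 83.5% with single TRP arrays). A loss of precision is a candidate explanation, since the size of the changes with the batch term was 0.88 of that without for TRPnull and 0.93 for TRPhet, while the standard errors rose 1.67-fold and 1.65-fold, but precision alone does not account for the TRPnull count, which with the batch term was 2363 without replicate 5 and 2237 without control replicate 2, at median standard errors of 0.326 and 0.301, against 0.293 with all arrays. Part of the changes may still come from batch, which no controls within batches 1 or 8 could separate. An effect of the genotype stays open.

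The animal that gave TRPnull replicate 5 in both tissues lay nearer to the controls than the other TRPnull animals, by 0.806 in T score in the bulb and 0.732 in the forebrain, with the probes of the score chosen without this animal. A shift of batch 8 was argued against, as the 5 other forebrain arrays with T of that batch whose genotype was also in other batches fell short by -0.18 of this animal's shortfall. An animal without T was argued against, since the bulb T score of -1.07 lay 0.57 above the highest bulb without T (SD 0.17), while the forebrain score of -1.28 lay in a range shared by arrays with and without T. An animal without R, as open as a weaker effect in this animal, may explain the R scores, which were -1.49 in the bulb and -1.51 in the forebrain. They lay below every other TRP bulb (lowest -1.29) and every other forebrain array with T and R (lowest -1.22). The probes of the R score were chosen on the other TRP and TP bulbs. A bulb left out of that choice can score between the groups for that reason alone. At 56.3% of 286 separating probes, however, the bulb array lay beyond every TP array. TP arrays left out in turn gave 2.1% to 17.5%, apart from 84.2% in TPhet replicate 5, also of batch 8, and TRP arrays gave 62.2% to 99%. An exchange with the TPhet animal of that batch was not settled. The R scores of that TPhet animal, -1.45 in the forebrain and -1.30 in the bulb, lay among T arrays without R (-1.93 to -1.31 and -2.05 to -1.13), as its own label predicts. Its bulb score, however, was the highest of the TP bulbs, passed only by bulbs of T alone, and was next to the lowest T bulb with R (-1.29). Its bulb T score of -0.114 lay above the means of TRP bulbs (-0.258) and TP bulbs (-0.689). Between the bulbs of these animals, only 36% of the R calls from the other batches kept their sign. These last values go with an exchange. Single probes were divided. At A_51_P351975, TRPnull replicate 5 stood at -1.80, above every TP bulb (highest -2.92, TPhet replicate 5) and below every other TRP bulb (lowest -1.21). At A_52_P707503 replicates 5 of TRPnull and TPhet stood at -0.04 and 3.56, each on its own label's side, as at A_52_P37991 (1.87 and 4.31). At A_51_P230098 they stood at -2.12 and 0.48, on the side of an exchange. These probes were named from fits with both arrays, so they cannot decide.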

How the results depend on the processing

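Fits without the 3 arrays far out on the third component, without the animal of TRPnull replicate 5, and within batches for TRPnull against TRPhet and for forebrain T and TPhet, the scaling of the spread and its values with arrays left out, and everything on the T score and the added effects were chosen after the data were seen. In all, 369 settings left a count within 1.5 times or a value on its side of the threshold and 153 did not; of 836 settings for single named probes, 705 left the call, 131 lost it and 0 reversed it. Of the losses, 36 were at forebrain TRPnull probes, 27 at TPhet and 19 at T there, 16 (all that were run) at the tissue difference of TRPnull, and 5, 7, 9, 4 and 5 at bulb T, TPhet, TPnull, TRPhet and TRPnull against TRPhet, with 3 at the additive T effect in the forebrain. The cause was not tested, except that fits within a batch or of the compared groups alone use fewer arrays and the more variable probes alone are fewer. The estimation of array weights stopped short of its tolerance in some fits, so those counts are the least certain. Signal over background was not available here, so what dim probes limit is unknown. Gene lists and the choice among a gene's probes were not run, and a filter on missing values moved nothing.

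In the bulb, batch left out gave 3813 probes for TPnull, 79 for the Pnull effect, 2827 for the interaction of T and R and 20 for TRPnull against TRPhet. Batch as a random block gave 7686 for T, 1 each for Phet, Pnull and RPhet, 4142 for TPnull, 1418 and 381 for the Phet and Pnull effects, 2927 for the interaction and 30 for TRPnull against TRPhet. Array weights gave 13688 for T, 972 for Pnull, 6783 for TPhet, 8083 for TPnull, 5 for RPhet, 1 for RPnull, 16037 for TRPhet, 1 for the Pnull effect, 4490 for the interaction and 9006 for T without R. The compared groups alone gave 1175 for T, 1302 for TPnull, 11 for RPnull and 0 for TRPnull against TRPhet (2159 unadjusted with all arrays, limma). Within batch 4 the counts were 133 for TPhet, 812 for TPnull, 1702 for TRPhet, 6467 for TRPnull and 0 for TRPnull against TRPhet. Within batch 5 they were 1250 for T, 14 for Pnull, 174 for TPhet, 201 for TPnull, 12 for RPhet, 327 for RPnull, 510 for TRPhet, 450 for TRPnull and 48 for TRPnull against TRPhet; apart from T with 2 arrays, each compared 1 array with 1, with the spread taken from the T pair alone, so these counts are weak evidence. The more variable probes alone gave 10923 for the T effect, and T without the 3 arrays of the third component gave 2582.

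In the forebrain, batch left out gave 1451 for T, 500 for TPhet, 6959 for TRPhet, 7277 for TRPnull, 3774 for the T effect and 885 for the R effect, and batch as a random block 1579, 446, 10136, 10694, 4014 and 2162. For the R effect these fits cannot separate R from batch, since R varied only within batch 8. Array weights gave 307 for T, 1 for TPhet, 729 for TRPhet, 808 for TRPnull, 4391 for the T effect and 1279 for the R effect. Quantile normalization gave 313 for T, 29 for TPhet (100% higher, against 84.4%), 0 for TRPnull and 1 for the R effect, and median centring 253 for TPhet, 14 for TRPhet and 3 for TRPnull (66.7% higher, against 40%). The more variable probes alone gave 284 for TPhet, 9 for TRPhet and 0 for TRPnull. Without the 3 arrays of the third component the counts were 227 for T, 1 for TPhet and 0 for TRPnull. TPhet gave 26 with the compared groups alone and 59 within batch 2, TRPhet 5 with the array of conflicting labels added as T, and TRPnull 2363 without the animal of replicate 5. TRPnull against TRPhet gave 1 within batch 1 (4 arrays a side) and 555 within batch 8, weak evidence, since its 1 TRPnull array, against 2 of TRPhet, was replicate 5, whose label is in doubt, and the 2 batches disagreed (correlation -0.26 across probes; 23.1% of the 481 probes called without batch 1 had the same sign within it).

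Bulb against forebrain was paired by animal, as the labels number the animals; without the pairing 13942 probes were called, against 16804 with it. The more variable probes alone gave 9780 and batch 8 alone 1218. The tissue difference of TRPnull gave 0 with batch left out, quantile normalization, median centring, the more variable probes, array weights or without the 3 arrays of the third component (6124 unadjusted as reported, limma).

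The difference in spread was 0.119 in the bulb and -0.0619 in the forebrain with quantile normalization, and 0.0807 and -0.0654 when scaled for the number of arrays. With quantile normalization the T score difference was -0.0518 for Phet and -0.00885 for RPnull, both turned in sign and neither past the threshold before or after, and 0.881 for forebrain TRPnull, where the exact p went from 0.0536 to 0.0357, past the threshold.

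With each array left out in turn, bulb counts ran from 2412 to 6711 for T, 1606 to 3140 for TPhet, 1374 to 3058 for TPnull, 8007 to 8892 for TRPhet, 9014 to 12518 for TRPnull and 0 to 1 for TRPnull against TRPhet. Forebrain counts ran from 1 to 3018 for T, 1 to 4373 for TPhet, 0 to 2339 for TRPhet and 0 to 2363 for TRPnull. The difference in spread ran from 0.0345 to 0.0927 in the bulb and -0.345 to -0.0576 in the forebrain. The T score difference ran from 0.808 to 1.23 for T, -0.0625 to 0.0905 for Phet, -0.0115 to 0.141 for Pnull, -0.0742 to 0.0787 for RPhet and -0.0704 to 0.104 for RPnull in the bulb, and 0.412 to 0.609 for T and 0.716 to 0.968 for TRPnull in the forebrain.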

Other observations

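The T score, the counts over other splits of the arrays and the effects of T and R with and without each other were chosen after the result was seen; the tests of tissue difference and of animals were set beforehand.

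The effect of T in bulbs with R ran along that in bulbs without R. Across probes, which are not independent, the effects correlated at 0.80, with a slope of 1.37 ± 0.22 (jackknife SE) of the effect with R on that without. Of the probes called for T without R, 97.8% had the same sign with R. Both lists shared 2813 rises, against 591 for independent lists, and 1503 falls, against 406.2, and 18 probes went opposite ways. A_51_P230098 rose by 4.58 ± 0.28 without R and 5.17 ± 0.28 with it, and A_51_P195034 by 5.32 ± 0.31 with it.

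Arrays of 1 animal with T may share deviations in both tissues, as a hypothesis. Over 19 animals the mean correlation of deviations from the group means was 0.158, positive in 16, against 0.001 when animals were paired at random (highest 0.234; one-sided permutation p = 0.007). In pairs whose arrays lay in 2 batches the mean correlation was 0.132. Both control animals, the only ones without T among the 19, were negative (-0.363 and -0.437). Deviations from the mean of few control arrays depend on each other. One of these animals gave forebrain control replicate 3, which lay far out on the third component. Sharing without T therefore could not be judged. A loss of tissue differences in TRP animals, the other hypothesis, could not be decided. Over 1434 probes the mean difference between tissues was 0.996 ± 0.18 (SD, n = 10) in TRP and 1.06 ± 0.20 (SD, n = 8) in other animals, a difference of -0.0588 (two-sided exact p = 0.521).

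The forebrain array whose title gave T and whose genotype field gave Phet had a T score of -1.39. Forebrain arrays of genotype T alone went down to -1.11, those with T of any genotype to -1.34, and the highest forebrain control stood at -1.26. The animal of this array also gave bulb Phet replicate 2, whose title and genotype both gave Phet. That bulb had a T score of -1.79, below the lowest bulb with T (-1.51). If the animal number is right, this argues for Phet.

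Other splits of the same arrays tested whether chance gives as many probes. Chance was excluded, with 1 split, the real one, reaching its count, for T against control in the bulb (5013, highest other 1347, 35 splits) and, over 100 splits, for TPhet (2884, 2344), TPnull (2491, 2452), TRPhet (10431, 1682) and TRPnull (11285, 9490). The highest others for TPhet, TPnull and TRPnull kept 1 array of the genotype with all 4 controls, nearly the real grouping. Of the 5 such splits of TRPnull, the one with replicate 5 among the controls, not among the 100 drawn, gave 12886, above the real count. Chance was also excluded for the additive effects of T (16854, 2) and R (3035, 1782) in the bulb, for R with T (8092, 421), T with R (13368, 162) and T without R (5107, 1275), for T in the forebrain against control (541, 0, 35 splits) and as an additive effect (2107, 675), and for bulb against forebrain (16804, 42).

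The other counts did not exclude chance or were not testable. A count of 0 is reached by every split by construction, so the splits say nothing on Phet (highest other 1) and RPhet (0) over 35 splits, on Pnull (0), RPnull (1), the additive effects of Phet (2) and Pnull (1), Pnull against Phet (348), R without T (1), R in the forebrain (2), forebrain TRPnull against TRPhet (above the 348 of Pnull against Phet) and the tissue difference of TRPhet (3821) over 100, and on forebrain TRPhet (1676) over 84; limma was the tool throughout. For the 1 probe of bulb TRPnull against TRPhet, 11 of 100 splits reached it (highest other 137), and for the 5 of forebrain TRPnull, 7 of 56 (1352). The highest splits of forebrain TRPhet and TRPnull parted batch 1 from batch 8, with control replicate 3 apart from the other controls, and no value within a batch could be had. For forebrain TPhet the 10 splits are too few for a share under 0.05 (147, highest other 1594).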
